A study of Solanum lycopersicum with 12 samples.

How the data were processed

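RNA was measured in leaves of wild-type tomato and of bsk830-1, a line in which the BSK830 gene (also called Fir1) was edited with CRISPR/Cas9. Leaves were vacuum-inoculated with Pseudomonas fluorescens or mock-inoculated and collected 6 h later, with 3 biological replicates per group per the labels, giving 12 libraries in 4 groups. Per the labels' protocols, total RNA was isolated with a QIAGEN plant kit and mRNA libraries were made with the NEBNext Ultra II kit. Alignment with STAR and processing in Partek are named per the submitters' processing notes, without versions. The genome build, the annotation and the strand setting are not given in the sources used here.

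The deposited table gives RPKM values (reads scaled to transcript length and library depth) from the authors, for 23338 genes named by Solyc identifiers in all 12 libraries, of which 2 were at 0 everywhere. RPKM totals ran from 292163 to 326626 per library. The low values of a gene were whole multiples of what 1 read is worth, which allowed read numbers to be recovered. With a tolerance of 0.1 read, whole reads came out for 22502 genes (96.4%). Among genes of 1 to 20 RPKM the share was 97.5%, against 0% of 571 genes in that range whose values had been shuffled between genes. Summed over all recovered genes, reads ran from 10.07 to 16.56 M per library, a range that sets the counting error of low genes. Genes that reached 15000 reads in a library could not be recovered, so the sums understate the depth. No pair of replicates was close enough to be a duplicate, since the chi-square of recovered reads was at least 14.41 times its degrees of freedom.

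Genes with an RPKM of at least 1 in at least 3 libraries were kept (16954 genes). Values were analysed as log2(RPKM + 1), a scale that understates the change of low genes. They were fitted with limma (version 3.58.1, in R 4.3.3) on 4 group means with an intensity trend in the variance, over all 12 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Contrasts were inoculated against mock leaves in each genotype, mutant against wild type under each inoculation, and the interaction. A contrast of the mean genotype difference was added after the separate ones had been seen. The targeted gene was tested with an exact two-sided permutation test. The size of the response was scored per library as the mean log2 value of 3764 risen genes minus that of 4897 fallen genes, chosen by the mean response of both genotypes. The interaction of the score was tested by exact permutation of genotype labels within each inoculation (400 arrangements). Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.

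Gene lists were fixed before the data were examined, as Solyc identifiers with the symbols of published tomato nomenclature. Of 233 listed identifiers 207 were in the table, and 26, among them FLS3, are not analysed here. A RefSeq gene table without Solyc identifiers served only to compare the chromosome of each symbol. By that comparison 86 symbols were on the same chromosome, 144 had no entry, and 3 members on another chromosome were dropped. Symbols therefore rest on nomenclature, and members of families are printed with their identifiers. Lists planned from gene descriptions alone (auxin response, calcium sensors, receptor-like kinases, glutathione transferases, cell wall enzymes, peroxidases, terpene synthases, aquaporins, ribosomal proteins, vascular tissue) could not be filled without an annotation. Of 19 lists with identifiers, 15 had at least 5 tested genes and were compared with all other genes by limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were also run. For the lists called by camera, unadjusted fry p ran from 1.35e-05 to 0.00823 in the wild-type response, 8.93e-06 to 0.0505 in the mutant response, 0.183 to 0.753 between genotypes in mock leaves and 0.157 to 0.652 for the interaction. Of the 15 lists, none was called in any contrast with an estimated correlation (0 calls in each of 6 contrasts). Near-identical family members, such as the chlorophyll a/b-binding genes, can share reads, and their single values are uncertain.

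Named genes followed a rule fixed before the data were examined. It takes the targeted gene, and the 5 risen and 5 fallen listed genes with the largest change among called genes whose groups do not overlap and whose higher mean is at least 5 RPKM. It adds up to 3 risen and 3 fallen called members of each list by adjusted p, and a set of defence and hormone genes whether called or not. Of the last set, JAZ1, JAZ2, MYC2, LOXD, NPR1, WRKY33, FLS2.1, RBOHB, MPK3, ACS2, NCED1 and BRI1 were tested. ICS1 was measured but did not pass the filter. Unlisted identifiers named for the genotype comparisons were chosen after their values were seen.

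The fits were tested on simulated data drawn from the real means and spreads of these libraries. Each run held 16954 genes, and the changed genes were pooled over runs to 250 per size. Changes of 1.5-, 2-, 4- and 8-fold were recovered for 21.6%, 55.6%, 90% and 94.4% in the wild-type response. For the interaction 2.4%, 32.8%, 67.2% and 87.6% were recovered. A far smaller share of genes was changed in each run than the 39.79% called in the real wild-type response. The adjusted p threshold was therefore stricter in the simulation, and its shares need not hold for that response. The list test found 30 of 30 simulated lists in which every member was moved 2-fold in the same direction, and 0 of 30 unmoved ones. Smaller moves, such as the interaction medians of the called lists, were not simulated. The simulated genes varied independently of each other, while the estimated correlation was 0.803 in the photosystem list. The simulation therefore cannot show how often the real lists are called falsely. The test of response size found 2 of 10 simulated mutant responses at 0.5 of the wild-type size, so it had little power.

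Alternatives covered the pseudocount (0.1), the filter (none, or an RPKM of at least 5), quantile normalization, median-ratio scaling, a replicate block, fits on the 6 libraries of a comparison, a 2-fold threshold, robust estimation with array weights, and each library left out in turn. The array weights ran from 0.209 (wild-type mock replicate 3) to 8.61 (inoculated wild-type replicate 3), so single libraries dominated some group means in that fit. Added after the data were seen were fits on replicates 2 and 3 alone, a term for replicate 1, voom on recovered reads, and a fit without the 2 libraries farthest from their group mates. Those 2 libraries in doubt were wild-type mock replicate 3 and inoculated mutant replicate 2. The term for replicate 1 was added because the labels number those 4 libraries in another series than the other 8, which may mark a sequencing batch with 1 library per group.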

Results

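Transcript levels were measured by RNA-seq in leaves of wild-type tomato and of the bsk830-1 mutant, 6 h after inoculation with P. fluorescens or mock inoculation, in 3 biological replicates per group (12 libraries). BSK830, or Fir1, is a receptor-like cytoplasmic kinase that interacts with the flagellin receptors Fls2 and Fls3, and P. fluorescens is a bacterium whose flagellin is perceived by the plant. The recovered read numbers were 15.4, 10.49 and 14.29 M reads in wild-type mock replicates 1 to 3 and 14.64, 10.07 and 14.76 M reads in inoculated wild type. They were 13.99, 12.44 and 12.85 M reads in mutant mock and 16.13, 10.18 and 16.56 M reads in inoculated mutant libraries. The first principal component held 71.9% of the variance and separated mock from inoculated libraries. On it, wild-type mock replicate 3 lay at -18.6, against -80.5 and -84.8 for its group mates. Mutant mock replicates 1 and 2 lay at -43.3 and -33.4, against -69.2 for replicate 3. On the second component (8.8% of the variance), inoculated mutant replicate 2 lay at -43, against 28.7 and -6.42 for its group mates.

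The targeted gene, BSK830 (Solyc12g099830), was lower in every mutant library than in every wild-type library. In mock leaves it measured 1.65 ± 0.109 RPKM in the mutant and 4.72 ± 0.252 RPKM in the wild type (SD, n = 3 each), 35% of the wild-type level. In inoculated leaves it measured 1.22 ± 0.0738 against 3.84 ± 0.797 RPKM (SD, n = 3 each), 31.8% of the wild-type level. The exact two-sided permutation p was 0.1 for each, the smallest that 3 against 3 libraries allow. With limma the log2 difference was -1.11 (SE 0.117) under both inoculations, at Benjamini-Hochberg adjusted p of 0.00466 (inoculated) and 0.00801 (mock). The mock call was lost without wild-type mock replicate 1 (limma adjusted p = 0.0553), mutant mock replicate 1 (0.0615), replicate 2 (0.0523) or replicate 3 (0.0784), while the log2 difference stayed between -1.14 and -1.08.

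**Figure D1:**
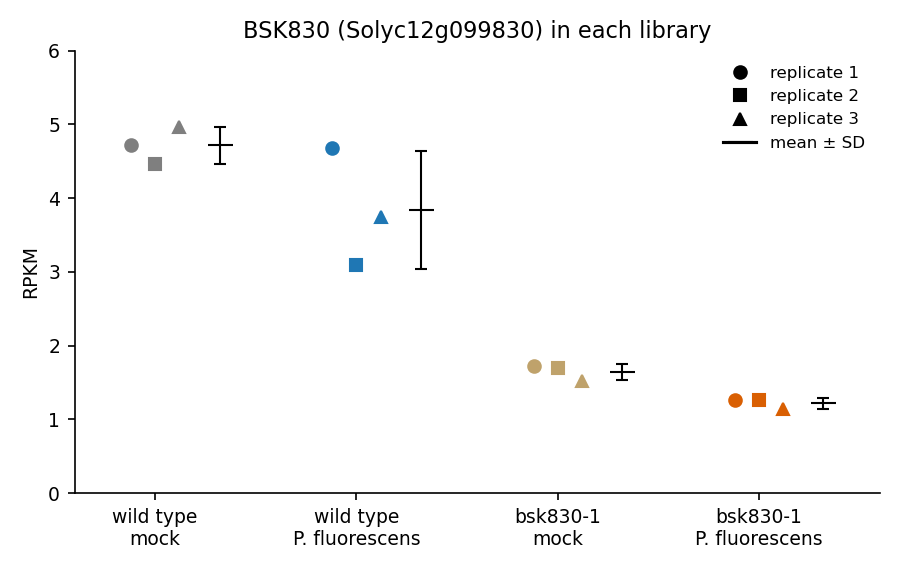
RPKM of the edited gene BSK830 in each of the 12 libraries, by group, with the mean and SD of 3 replicates beside the points. The mutant libraries lie between 1.137 and 1.719 RPKM, and the wild-type libraries between 3.096 and 4.97 RPKM.

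In wild-type leaves, NP24 (Solyc08g080640), an osmotin-type antifungal protein, rose from 8.75 ± 3.38 to 135 ± 15.7 RPKM. A PR-1 gene (Solyc01g106620), of the secreted pathogenesis-related proteins, rose from 48.1 ± 10.9 to 649 ± 84.1 RPKM. PSAD (Solyc06g054260), a subunit of photosystem I, fell from 1475 ± 684 to 214 ± 83.3 RPKM, and the polyphenol oxidase gene Solyc08g074620 fell from 555 ± 202 to 39.2 ± 19.7 RPKM (SD, n = 3 each). limma called 6746 of 16954 genes, 2954 higher and 3792 lower, of which 3196 changed at least 2-fold, and 8452 genes had an unadjusted p under 0.05. The excess of fallen genes depended on the settings, with 3529 higher and 3436 lower under quantile normalization and 6124 higher and 6004 lower under robust estimation with array weights. Of the 185 listed genes tested 62 rose and 47 fell.

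Pathogenesis-related proteins rose in 8 of 11 tested members, with 0 fallen and the same 8 when adjusted over the list alone (limma's camera adjusted p = 2.21e-05; adjusted p = 0.244 with an estimated correlation). Besides NP24 (log2 change 3.86, SE 0.41, limma adjusted p = 0.000504) and the PR-1 gene (3.74, SE 0.436, adjusted p = 0.000692), the chitinase gene Solyc10g055800 rose from 85.3 ± 33.5 to 472 ± 70.2 RPKM and the PR-5 type gene Solyc08g080650 from 21.8 ± 2.95 to 113 ± 25.4 RPKM (SD, n = 3 each). Genes of phenylpropanoid and lignin synthesis rose in 15 of 17 members and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 8.05e-08; adjusted p = 0.307 with an estimated correlation). Phenylalanine ammonia-lyase opens this pathway, and its genes Solyc05g056170, Solyc09g007910 and Solyc10g086180 had log2 changes of 3.46, 3.40 and 2.77. Solyc09g007910 rose from 5.12 ± 0.285 to 67.7 ± 27.1 RPKM (SD, n = 3 each). The caffeoyl-CoA O-methyltransferase gene Solyc02g093250 also rose (2.24, limma adjusted p = 0.000692). Wild-type mock replicate 3 stood above its group mates in Solyc05g056170, with 13.9 against 5.84 and 7.22 RPKM.

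Genes of jasmonate signalling rose in 9 of 17 members with 0 fallen, and in 11 adjusted over the list alone (camera adjusted p = 0.000133; adjusted p = 0.423 with an estimated correlation). The repressor JAZ2 (Solyc12g009220) rose from 7.41 ± 5.81 to 73.8 ± 21.9 RPKM, and the transcription factor genes JA2L and MTB1 had log2 changes of 1.78 and 1.49. The repressor JAZ1 (1.32, limma adjusted p = 0.108) and the regulator MYC2 (0.18, adjusted p = 0.498) were not called. JAZ1 measured 107, 66.9 and 24.6 RPKM in inoculated replicates 1 to 3. Genes of jasmonate synthesis rose in 4 of 6 members with 0 fallen, also adjusted over the list alone (camera adjusted p = 0.0256; adjusted p = 0.423 with an estimated correlation, and adjusted p = 0.0575 under quantile normalization). The lipoxygenase gene LOXD (Solyc03g122340) rose from 7.73 ± 2.94 to 68.3 ± 29.9 RPKM, the allene oxide synthase gene AOS1 had a log2 change of 3.14, and OPR3, for the reductase of the last plastid product, of 1.20. In AOS1, wild-type mock replicate 3 measured 45.4 RPKM against 8.96 and 13.1 in its group mates. Among 9 jasmonate- and wound-responsive defence proteins 1 rose and 4 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.22). The fallen ones included both polyphenol oxidase genes (Solyc08g074620, -3.85, limma adjusted p = 0.000689; Solyc08g074630, -3.62) and the threonine deaminase gene TD2 (-2.23). The proteinase inhibitor II-type gene Solyc03g020050 was listed at 0 in all wild-type mock libraries and measured 9.49, 1.72 and 1.05 RPKM in the inoculated ones.

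Pattern receptors and early signalling genes rose in 9 of 21 members and fell in 1, also adjusted over the list alone (camera adjusted p = 0.00862; adjusted p = 0.423 with an estimated correlation). The wall-associated kinase WAK1 (Solyc09g014720) rose from 1.71 ± 0.641 to 21.5 ± 6.43 RPKM (SD, n = 3 each; log2 change 3.04, limma adjusted p = 0.00037). The chitin-receptor kinase gene BTI9 (1.29), the flagellin receptor paralog FLS2.2 (1.89), the oxidase gene RBOHB of the oxidative burst (1.31) and the kinase gene MPK3 (1.23) also rose, and the co-receptor gene SERK1 fell (-0.60). The flagellin receptor gene FLS2.1 was not called (-0.84, limma adjusted p = 0.121). WRKY transcription factors rose in 5 of 11 members with 0 fallen, and in 6 adjusted over the list alone (camera adjusted p = 0.00213; adjusted p = 0.423 with an estimated correlation). Log2 changes were 2.62 for WRKY33, 2.02 for WRKY53 and 1.87 for WRKY31. Both lists were called without each library in turn.

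Photosystem and Rubisco genes fell in 30 of 31 members, also adjusted over the list alone (camera adjusted p = 8.05e-09; adjusted p = 0.423 with an estimated correlation). The chlorophyll a/b-binding genes Solyc02g071010, Solyc02g070970, Solyc02g071000 and Solyc02g071030, of the light-harvesting antenna, had log2 changes of -4.94, -4.21, -4.04 and -3.96. Solyc02g071010 fell from 230 ± 167 to 5.42 ± 2.38 RPKM, and the antenna gene Solyc05g056050 from 102 ± 61.9 to 7.39 ± 2.94 RPKM (SD, n = 3 each). In PSAD, wild-type mock replicate 3 lay closer to the inoculated libraries, at 702 RPKM against 1720 and 2004 RPKM in its group mates and 161 to 310 RPKM in inoculated leaves. Of the stomatal genes, which mark guard cells, MYB60 (-0.99) and OST1 (-0.52) fell and FAMA was not called. The trichome regulator MYC1, the only tested trichome gene (1 of 4 in the table), was not called (-0.77, limma adjusted p = 0.162).

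**Figure D2:**
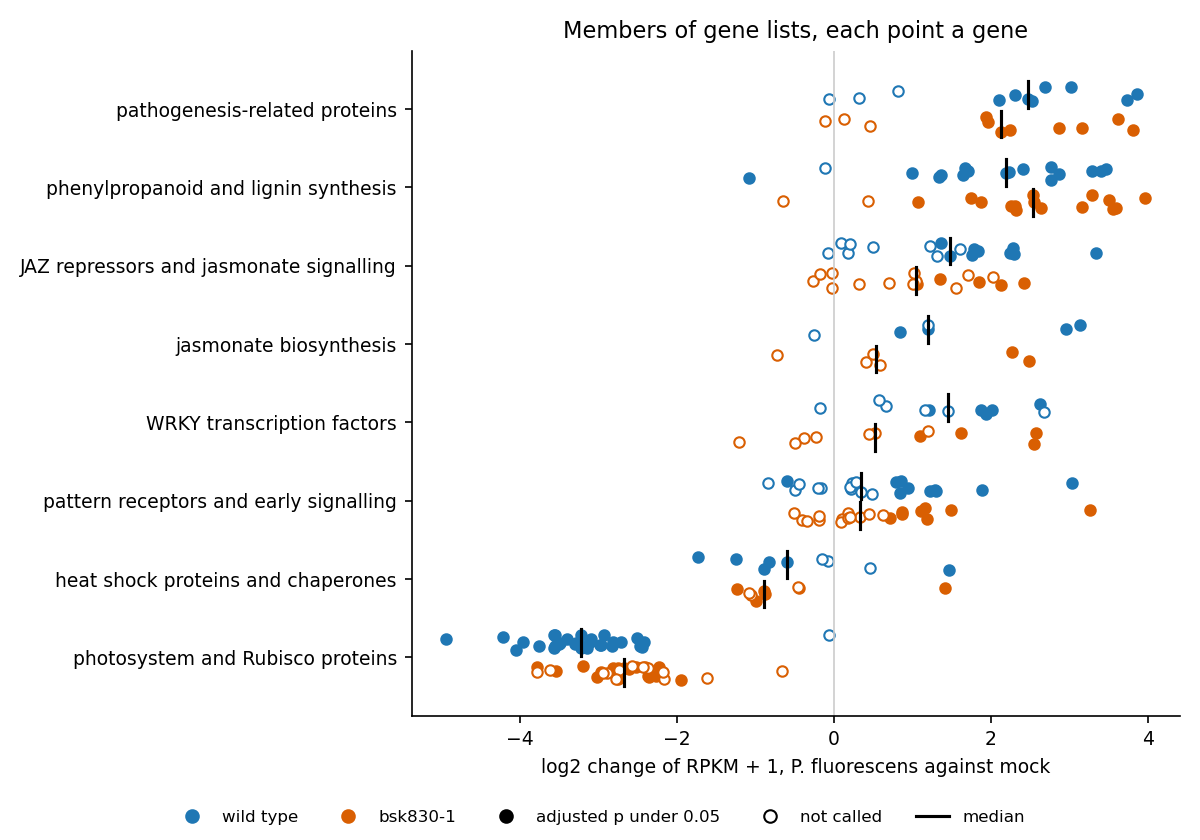
Log2 change of RPKM + 1 between inoculated and mock leaves for every tested member of 8 gene lists, in wild type and in the mutant, with filled points for called genes and a bar at the median. In the wild type 30 of 31 photosystem and Rubisco genes fell, and 15 of 17 phenylpropanoid genes rose.

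In the remaining groups some genes rose and others fell in the wild type, and camera called none of those with a set test (0 calls). The ERF and salicylate lists were too small to test. The ethylene synthesis gene ACS2 (3.27) and the receptor gene ETR4 (1.33) rose, and the list had 3 of 6 members risen and 0 fallen (adjusted p = 0.22). ACS2 measured 0.777 ± 1.18 RPKM in mock and 20.3 ± 22 RPKM in inoculated leaves (SD, n = 3 each), with 45.6 RPKM in inoculated replicate 2. The ERF gene PTI5 rose (2.49), 1 of 3 members. Of the abscisic acid genes 3 of 12 rose, namely the phosphatase gene Solyc03g096670 (2.75), LE4 (1.30) and AREB1 (0.93), and the zeaxanthin epoxidase gene ZEP fell (-1.87, limma adjusted p = 0.00832; list adjusted p = 0.169). The synthesis gene NCED1 was not called (1.31, limma adjusted p = 0.233). In the brassinosteroid list 2 of 5 fell, BZR1 (Solyc04g079980, -1.13) and CPD (-0.64). Its median was 0.01 and its mean -0.18, its test pointed down (adjusted p = 0.491), and the receptor gene BRI1 was at 0.13 (limma adjusted p = 0.664). Of 6 BSK genes 1 rose, Solyc10g085000 (1.20; list adjusted p = 0.491). The clock gene TOC1 rose (0.93) and FKF1 fell (-0.84), 2 of 6 members (list adjusted p = 0.852). The chaperone gene BIP rose (1.47) while HSFA2 (-1.73), HSP21 (-0.89), Solyc06g076520 (-0.83) and 2 other heat shock genes fell, of 9 members (list adjusted p = 0.169). BIP measured 134 RPKM in wild-type mock replicate 3, against 38.7 and 56.6 in its group mates. NPR1, the salicylate co-regulator, rose (0.84, limma adjusted p = 0.0182), 1 of 4 salicylate genes tested. The salicylate synthesis gene ICS1 did not pass the filter and was not tested. It measured 0.96, 1.43 and 0.27 RPKM in mock and 0.21, 0.18 and 0.09 RPKM in inoculated wild-type leaves. None of 7 reference genes was called (0 calls, list adjusted p = 0.491). Adjusted over the list alone, the counts of these lists with set tests did not differ.

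**Figure D3:**
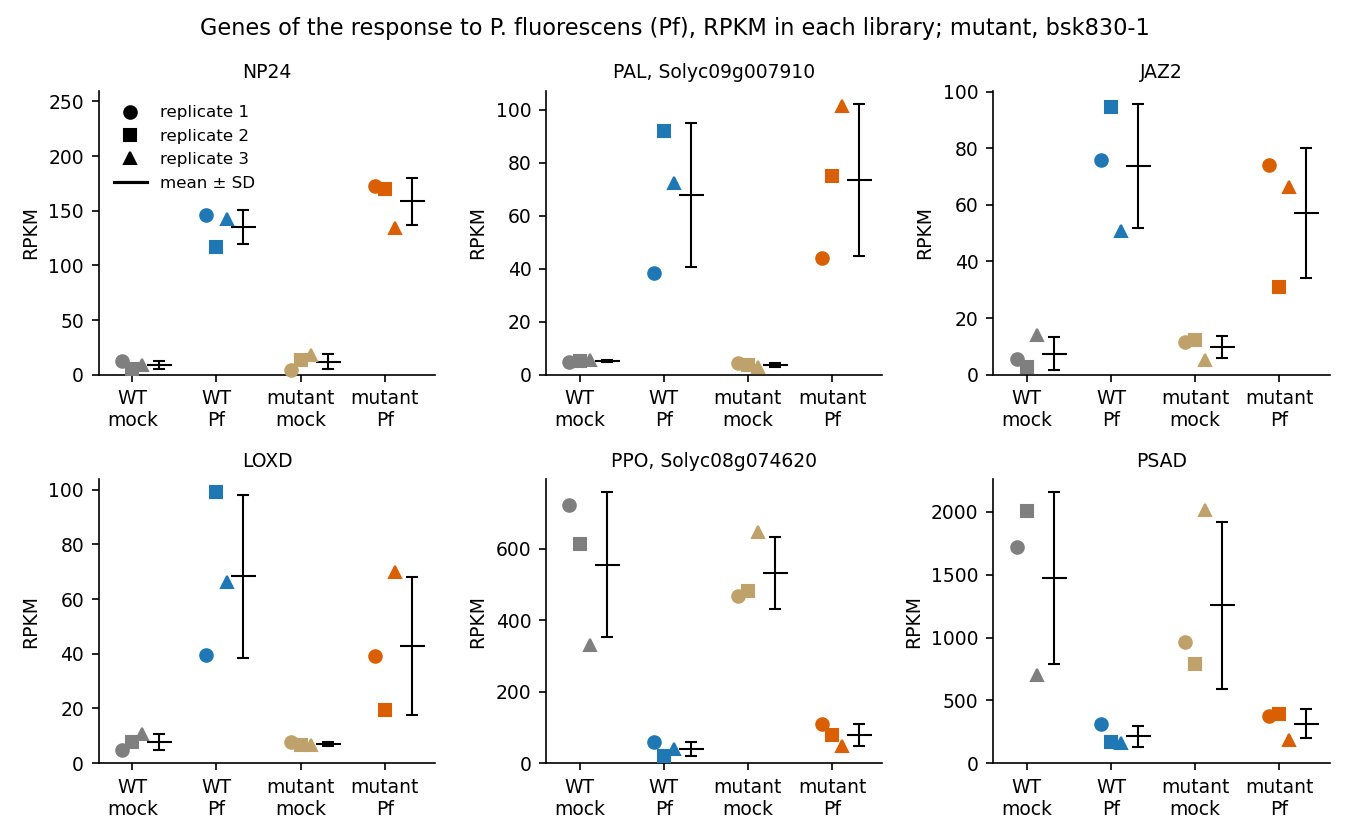
RPKM of 6 genes in each library, by group, with the mean and SD of 3 replicates beside the points. NP24, a phenylalanine ammonia-lyase gene, JAZ2 and LOXD were higher after inoculation in both genotypes, and a polyphenol oxidase gene and PSAD were lower.

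The wild-type count depended on single libraries. Without mock replicate 1 limma called 3838 genes, without mock replicate 2 3614, without inoculated replicate 2 3727 and without inoculated replicate 3 4073, against 8376 (4239 higher, 4137 lower) without mock replicate 3. Of the 109 called listed genes, 66 were called in every fit without 1 library. The numbers lost were 28, 42 and 5 without mock replicates 1, 2 and 3, and 13, 33 and 30 without inoculated replicates 1, 2 and 3. Among the genes named above, those lost in at least 1 such fit were Solyc02g070970, Solyc02g071000, NPR1, Solyc03g096670, LE4, AREB1, CPD, FKF1, ETR4, SERK1, OST1, BIP, OPR3 and TD2, with adjusted p of at most 0.15. No called listed gene changed sign under any scaling. Within replicates 2 and 3 alone, whose labels follow another numbering than replicate 1, 3187 genes were called, and 7435 with a term for replicate 1.

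In mutant leaves, NP24 rose from 11.8 ± 6.77 to 159 ± 21.6 RPKM, and the phenylalanine ammonia-lyase gene Solyc09g007910 from 3.57 ± 0.846 to 73.5 ± 28.9 RPKM. LOXD rose from 7.04 ± 0.704 to 42.9 ± 25.3 RPKM and JAZ2 from 9.70 ± 3.91 to 57.2 ± 23.1 RPKM, while the polyphenol oxidase gene Solyc08g074620 fell from 531 ± 100 to 78.4 ± 31 RPKM (SD, n = 3 each). limma called 3021 genes, 1337 higher and 1684 lower (44.3% higher), with 1612 changed at least 2-fold and 6223 at an unadjusted p under 0.05. With quantile normalization the split was 1678 higher and 1341 lower of 3019 (55.6% higher), and with median-ratio scaling 1604 and 1343 of 2947 (54.4%). Of 185 listed genes 48 rose and 30 fell.

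Phenylpropanoid genes rose in 15 of 17 members with 0 fallen, also adjusted over the list alone (camera adjusted p = 5.18e-14; adjusted p = 0.0754 with an estimated correlation). Log2 changes were 3.96 for Solyc09g007910, 3.56 for Solyc05g056170, 3.29 for Solyc10g086180, 3.16 for Solyc02g093250 and 3.59 for Solyc08g068710, a tyramine hydroxycinnamoyltransferase gene. Pathogenesis-related proteins rose in 8 of 11 with 0 fallen, also adjusted over the list alone (camera adjusted p = 4.66e-07; adjusted p = 0.0754 with an estimated correlation), among them NP24 (3.81), the PR-1 gene Solyc01g106620 (3.62) and Solyc08g080650 (1.96). The PR-1 gene measured 1366 RPKM in inoculated replicate 2 and 399 and 435 RPKM in its group mates. Jasmonate signalling genes rose in 5 of 17 with 0 fallen, and in 9 adjusted over the list alone (camera adjusted p = 0.000495; adjusted p = 0.431 with an estimated correlation), with JAZ2 at 2.43, JA2L at 1.35 and MTB1 at 1.06. Some members stood far higher in inoculated replicate 1 than in replicates 2 and 3, such as JAZ1 (107 against 27.7 and 23 RPKM) and JAZ7 (29.6 against 8.66 and 6.04 RPKM). Others did not, such as JAZ2 (74.2 against 30.9 and 66.4 RPKM). Jasmonate synthesis genes rose in 2 of 6, LOXD (2.28) and AOS1 (2.48), also adjusted over the list alone, and the list was not called (camera adjusted p = 0.105), but was without inoculated mutant replicate 2 (0.0345). In inoculated mutant replicates 1 to 3, LOXD measured 39.3, 19.6 and 69.8 RPKM and AOS1 87.3, 78.7 and 305 RPKM. Of the defence proteins 1 of 9 rose and 2 fell, both polyphenol oxidase genes (-2.81 and -2.55), also adjusted over the list alone (camera adjusted p = 0.418). Solyc03g020050 measured 0, 0.109 and 0 RPKM in mock and 4.7, 4.5 and 2.12 RPKM in inoculated mutant leaves.

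Pattern receptors and early signalling genes rose in 8 of 21 mutant members with 0 fallen, and in 9 adjusted over the list alone (camera adjusted p = 0.0013; adjusted p = 0.4 with an estimated correlation), with WAK1 at 3.27, BTI9 at 1.12, RBOHB at 1.16 and MPK3 at 1.19. WRKY genes rose in 4 of 11 with 0 fallen, and in 5 adjusted over the list alone (camera adjusted p = 0.00598; adjusted p = 0.431 with an estimated correlation), with WRKY53 at 2.55, WRKY33 at 2.57 and WRKY39 at 1.10. Photosystem and Rubisco genes fell in 18 of 31, and in 30 adjusted over the list alone (camera adjusted p = 2.54e-09; adjusted p = 0.431 with an estimated correlation). The antenna gene Solyc02g071010 (-3.79) measured 859 RPKM in mutant mock replicate 3 and 38.7 and 49.7 RPKM in replicates 1 and 2. Other antenna genes were Solyc02g071030 (-3.54), Solyc01g105050 (-3.20), Solyc10g007690 (-3.01) and CAB4 (-2.97). The stomatal genes MYB60 (-0.82, limma adjusted p = 0.027) and OST1 (-0.48, adjusted p = 0.0445) fell in the mutant too. Heat shock genes fell in 4 of 9 and rose in 1, with 5 fallen adjusted over the list alone (camera adjusted p = 0.0204; adjusted p = 0.392 with an estimated correlation), including HSP21 (-0.99), Solyc05g014280 (-0.89) and Solyc06g076520 (-0.87). That call was lost without mutant mock replicate 3 (0.0541) or inoculated mutant replicate 1 (0.0556). The other lists were not called, with camera adjusted p from 0.209 to 0.912. Of 12 abscisic acid genes 1 rose and 1 fell (2 and 1 adjusted over the list alone), of 6 ethylene genes 0 rose and 1 fell (3 and 1), of 5 brassinosteroid genes 2 fell, and of 6 BSK and 6 clock genes 1 each rose. In the clock list the median (-0.13) and mean (-0.07) lay below 0 and the test pointed up. ACS2 was at 2.09 (limma adjusted p = 0.0828) and NPR1 at 0.23 (adjusted p = 0.501), neither called, and ACO4, of ethylene synthesis, fell (-0.96, adjusted p = 0.036).

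The mutant count also moved with single libraries. limma called 1486, 1785 and 954 genes without mutant mock replicates 1, 2 and 3, 973 without inoculated mutant replicate 3, and 4632 without wild-type mock replicate 3, which enters through the shared estimate of spread. Of 78 called listed genes, 31 were called in every fit without 1 library, with 27, 21 and 45 lost without mutant mock replicates 1, 2 and 3 and 17, 9 and 45 without inoculated mutant replicates 1, 2 and 3. Among the genes named for the mutant, calls of MTB1, JA2L, JAZ2, AOS1, Solyc03g020050, RBOHB, MPK3, WRKY39, ACO4, Solyc06g076520, Solyc02g071010, Solyc02g071030, Solyc01g105050, Solyc10g007690, CAB4, MYB60 and OST1 were lost in at least 1 such fit, with adjusted p of at most 0.177. Leaving out wild-type libraries lost 11, 6 and 0 calls (mock) and 3, 12 and 11 (inoculated). Within replicates 2 and 3 alone 962 genes were called, and 4328 with a term for replicate 1.

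The responses of the genotypes were compared directly. Of the genes called, 2817 were called in both, 1251 higher and 1566 lower in both and 0 in opposite directions, against 233 and 376.7 for independent lists, and the genotypes share no library. Both responses share an estimate of spread per gene, however, so the lists are not fully independent. Across genes, which are not independent replicates, the log2 changes had a Pearson r of 0.945 and a Spearman rho of 0.926. Of 3929 genes called in the wild type alone, 99.3% had the same sign in the mutant, and 204 were called in the mutant alone. The response score rose by 2.09 in the wild type, from -0.63 ± 0.588 to 1.46 ± 0.381, and by 1.66 in the mutant, from -0.422 ± 0.281 to 1.24 ± 0.349 (log2 units, SD, n = 3 each). The mutant response was 79.8% of the wild-type one, a difference of -0.422 that was within the spread between libraries (exact two-sided permutation p = 0.405). The difference was -0.79 (exact p = 0.095) without wild-type mock replicate 3, -0.666 without inoculated wild-type replicate 1 and -0.64 without inoculated mutant replicate 3. It was -0.25 without wild-type mock replicate 2 (exact p = 0.625) and -0.274 without inoculated mutant replicate 1.

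**Figure D4:**
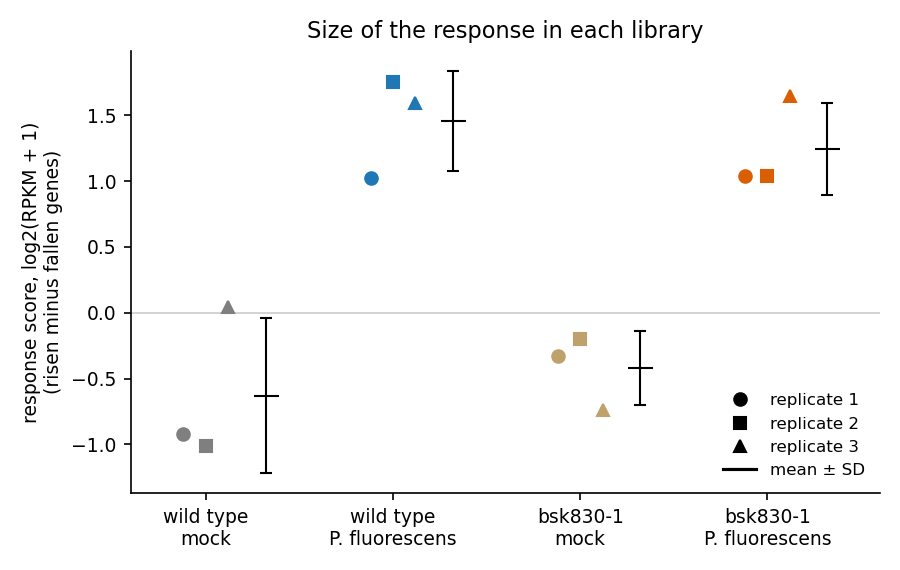
Response score of each library, the mean log2(RPKM + 1) of 3764 risen genes minus that of 4897 fallen genes (genes not centred over the libraries), by group, with the mean and SD of 3 replicates. Wild-type mock replicate 3, at 0.046, lies above the other mock libraries, which run from -1.015 to -0.2.

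Between genotypes, the question was which transcripts the mutation changes during the response. In inoculated leaves BSK830 was lower in the mutant and 6 genes were higher. Solyc10g084960 rose from 5.16 ± 1.13 RPKM in wild type to 109 ± 4.77 RPKM in the mutant, and Solyc03g116190 from 0.144 ± 0.13 to 4.15 ± 0.271 RPKM (SD, n = 3 each). Their log2 differences were 4.18 (SE 0.378, limma adjusted p = 0.0018) and 2.17 (SE 0.152, adjusted p = 0.000479). The file does not pair these identifiers with names, and both were chosen after their values were seen. limma called 7 of 16954 genes, 6 higher and 1 lower, and 461 had an unadjusted p under 0.05. With median-ratio scaling the split was 6 higher and 2 lower (75% higher, against 85.7%). With the 6 libraries of the comparison alone 2 genes were called, with the stricter filter 3, and with replicates 2 and 3 alone 0, where 540 genes had an unadjusted p under 0.05. Robust estimation with array weights called 15, 10 higher and 5 lower. Of 185 listed genes 1 was called, BSK830. Among the 12 defence and hormone genes named by rule, log2 differences ran from -1.04 (ACS2) to 0.94 (FLS2.1), with LOXD at -0.74, JAZ2 at -0.41, JAZ1 at -0.45, MYC2 at -0.32, NPR1 at -0.45, WRKY33 at -0.08, RBOHB at -0.11, MPK3 at 0.09, NCED1 at -0.90 and BRI1 at -0.04, none called (limma adjusted p = 0.998 each).

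Camera called 0 of 15 lists between the genotypes in inoculated leaves, with 1 list under an unadjusted p of 0.05, and 0 with an estimated correlation. The jasmonate signalling list came nearest, with a median of -0.17 and 15 of 17 members below 0 (camera adjusted p = 0.0667). It was called without wild-type mock replicate 2 (0.0443), inoculated wild-type replicate 3 (9.57e-08) or inoculated mutant replicate 1 (3.39e-05). Phenylpropanoid genes were called without inoculated wild-type replicate 2 (0.00107) or inoculated mutant replicate 1 (6.94e-05). WRKY genes were called without wild-type mock replicate 2 (0.0443) or inoculated wild-type replicate 1 (0.019), defence proteins without inoculated wild-type replicate 1 (0.00351), and photosystem genes without inoculated mutant replicate 3 (0.0286). In the BSK list, which includes the edited gene, the median was 0.01 and the mean -0.13, and in the pattern receptor list the median was -0.02 and the mean 0.05, and both tests pointed down.

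**Figure D5:**
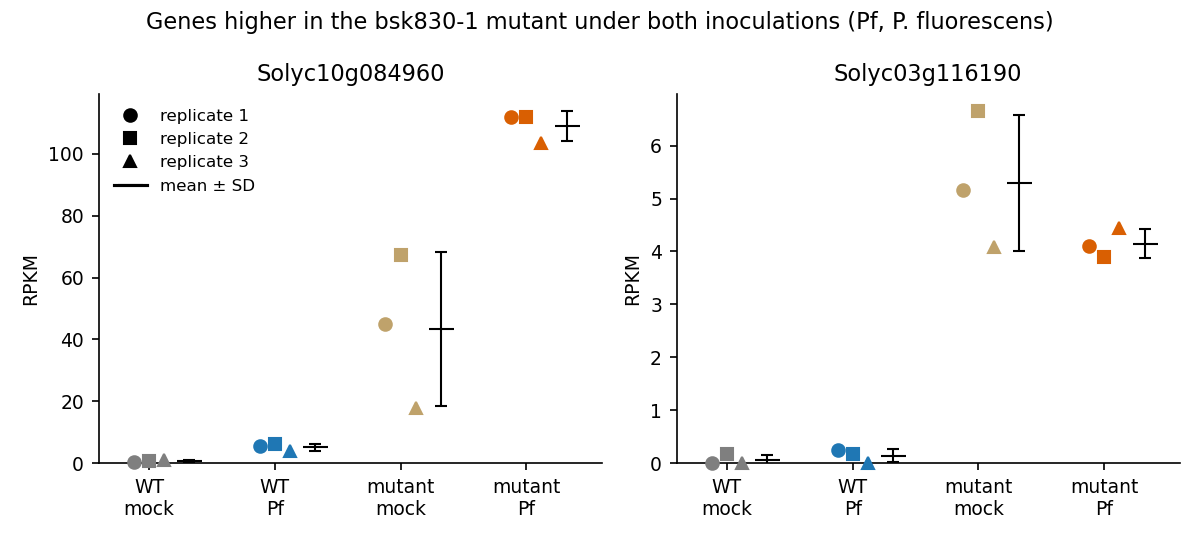
RPKM in each library of Solyc10g084960 and Solyc03g116190, which were higher in the mutant under both inoculations, by group, with the mean and SD of 3 replicates. Mutant libraries of Solyc10g084960 lie between 17.8 and 111.9 RPKM, and wild-type libraries between 0.391 and 6.13 RPKM.

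In mock leaves the same comparison gives the difference between the genotypes without the bacterium. BSK830 was lower and 5 genes were higher in the mutant. Solyc10g084960 measured 43.4 ± 24.8 RPKM in the mutant and 0.665 ± 0.29 RPKM in wild type, a log2 difference of 4.56 (SE 0.378, limma adjusted p = 0.00101). Solyc03g116190 measured 5.30 ± 1.29 against 0.0557 ± 0.0964 RPKM (SD, n = 3 each), a log2 difference of 2.56 (SE 0.152, adjusted p = 6.89e-05). limma called 6 genes, 195 had an unadjusted p under 0.05, and 4 genes, 3 higher and 1 lower, were called under both inoculations, against 0.00177 and 5.9e-05 for independent lists. The lists are not independent, since both contrasts share an estimate of spread per gene, and the lower gene is BSK830. Without mutant mock replicate 1 or mutant mock replicate 3, 3 genes were called. With the 6 libraries alone 2 genes were called, with the stricter filter 1, and with replicates 2 and 3 alone 0, where 117 genes had an unadjusted p under 0.05. Robust estimation with array weights called 18, 17 higher and 1 lower, with 4645 at an unadjusted p under 0.05. That fit gave wild-type mock replicate 3 a weight of 0.209, against 2.78 and 0.876 for its group mates. The named defence and hormone genes lay between -0.88 (NCED1) and 0.50 (JAZ2), none called (limma adjusted p = 1 each), with JAZ1 at 0.17, LOXD at -0.06, MYC2 at 0.03, NPR1 at 0.16, WRKY33 at -0.03, FLS2.1 at -0.24, RBOHB at 0.04, MPK3 at 0.13, ACS2 at 0.14 and BRI1 at 0.06.

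Camera called 3 lists between the genotypes in mock leaves, with 0 members called in each, also adjusted over the list alone. Phenylpropanoid genes were lower in the mutant as a list (median -0.37, 13 of 17 below 0, camera adjusted p = 1.49e-05; adjusted p = 0.687 with an estimated correlation), a call lost without wild-type mock replicate 3 (0.109). Photosystem and Rubisco genes were lower as a list (median -0.28, 27 of 31 below 0, adjusted p = 0.01; adjusted p = 0.997 with an estimated correlation). That call was lost without wild-type mock replicate 1 (0.0717) or replicate 2 (0.468) or mutant mock replicate 1 (0.638) or replicate 2 (0.977), and under quantile normalization (0.0758). Jasmonate synthesis genes were higher as a list (median 0.44, 5 of 6 above 0, adjusted p = 0.0329; adjusted p = 0.687 with an estimated correlation). That call was lost without wild-type mock replicate 1 (0.409), 2 (0.0676) or 3 (0.0978), or mutant mock replicate 2 (0.0577) or 3 (0.285). Wild-type mock replicate 3 stood apart from its group mates in PSAD (702 RPKM) and AOS1 (45.4 RPKM). The BSK list, which includes the edited gene as its only called member (1 of 6), was called without wild-type mock replicate 2 (0.00992) or mutant mock replicate 2 (0.0292), heat shock genes without mutant mock replicate 1 (0.0133), and WRKY genes without wild-type mock replicate 2 (0.00992). In the BSK, pathogenesis-related and reference lists the medians (0.05, 0.06 and 0.01) lay above 0 and the tests pointed down.

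The interaction asks whether the response itself differed between genotypes. No single gene was called, and the 2 caffeoyl-CoA O-methyltransferase genes Solyc02g093230 (0.98, unadjusted p = 0.0154 by limma, adjusted p = 0.999) and Solyc02g093250 (0.93, adjusted p = 0.999) had the lowest p of the listed genes. limma called 0 genes, with 175 at an unadjusted p under 0.05 and a smallest adjusted p of 0.812. The gene with that adjusted p, which the files do not pair with a name, was listed at 0 in all wild-type mock libraries. It measured 0.152 ± 0.131 RPKM in inoculated wild type, 1.43 ± 0.756 RPKM in mutant mock and 18.3 ± 8.24 RPKM in inoculated mutant leaves (SD, n = 3 each). voom on recovered reads called 0 of the 16245 genes it could test, with 128 at an unadjusted p under 0.05, and robust estimation with array weights 0, with 4468.

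As lists, phenylpropanoid genes had a larger rise in the mutant (median 0.43, 16 of 17 above 0, camera adjusted p = 0.000188; adjusted p = 0.751 with an estimated correlation). Photosystem and Rubisco genes had a smaller fall (median 0.58, 28 of 31 above 0, adjusted p = 0.0159; adjusted p = 0.765 with an estimated correlation). Jasmonate synthesis genes had a smaller rise (median -0.63, 6 of 6 below 0, adjusted p = 0.0234; adjusted p = 0.751 with an estimated correlation), as did jasmonate signalling genes (median -0.34, 15 of 17 below 0, adjusted p = 0.0199; adjusted p = 0.765 with an estimated correlation). Each list had 0 called members, also adjusted over the list alone. Of these, the phenylpropanoid, photosystem and jasmonate synthesis lists were also called between the genotypes in mock leaves (medians -0.37, -0.28 and 0.44). Their medians in inoculated leaves were 0.12, 0.29 and -0.13, and camera called none of them there (adjusted p = 0.217, 0.326 and 0.338). The interaction of these lists therefore includes the difference in mock leaves with its sign turned. The phenylpropanoid call was lost without wild-type mock replicate 3 (0.0577), inoculated wild-type replicate 1 (0.138) or inoculated mutant replicate 3 (0.103). The photosystem call was lost without wild-type mock replicate 2 (0.949), inoculated wild-type replicate 3 (0.232), mutant mock replicate 1 (0.824) or 2 (0.708), or inoculated mutant replicate 1 (0.247) or 2 (0.147). The jasmonate synthesis call was lost without wild-type mock replicate 1 (0.106), 2 (0.0522) or 3 (0.0577), inoculated wild-type replicate 2 (0.0688), mutant mock replicate 2 (0.0626) or 3 (0.131), or inoculated mutant replicate 2 (0.226). The jasmonate signalling call was lost without wild-type mock replicate 2 (0.0841) or 3 (0.0577), inoculated wild-type replicate 1 (0.688) or 2 (0.0688), mutant mock replicate 2 (0.069), or inoculated mutant replicate 2 (0.664) or 3 (0.103). Defence proteins, not called (0.0686), were called without wild-type mock replicate 1 (0.0135), inoculated wild-type replicate 1 (0.00219), mutant mock replicate 3 (0.0181) or inoculated mutant replicate 2 (0.0156), and WRKY genes (0.222) without wild-type mock replicate 1 (0.0238) or inoculated wild-type replicate 1 (0.0354). In the BSK list the median (0.01) lay above 0 and the test pointed down.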

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

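The interaction test of the lists was planned, and the tests of explanations and the counts of splits in this part were chosen after the results they bear on had been seen.

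The interaction test of camera called 4 lists at the preset correlation and 0 with an estimated correlation, with adjusted p of 0.0234 for jasmonate synthesis (0.751 with an estimated correlation), 0.0199 for jasmonate signalling (0.765), 0.000188 for phenylpropanoid synthesis (0.751) and 0.0159 for photosystem and Rubisco genes (0.765). Of these lists 0 stayed called in every fit without 1 library, and they stayed called in 5, 5, 9 and 6 of 12 such fits in that order. Since each call was lost without any of several libraries, these fits cannot tell a call resting on 1 library from a weak call in smaller groups. In 3 lists, jasmonate synthesis, jasmonate signalling and photosystem genes, the interaction median had the opposite sign to the wild-type response. Any smaller response in the mutant gives that sign, so it cannot tell an evenly smaller response from one smaller in these lists. Median log2 changes in wild type and mutant were 1.2 and 0.542, 1.49 and 1.04, and -3.22 and -2.68 in that order. For phenylpropanoid genes, which rose in the wild type, the interaction median of 0.427 has the other sign. It was within the spread between libraries (exact permutation p = 0.215 of the list mean). So were the means of the other 3 lists (exact p = 0.195, 0.485 and 0.625 in that order), and an evenly smaller response stays open for all 4. An effect of the mutation on these pathways stays open, and 41 of 100 splits of the libraries gave as many called lists (4 in the real split, at most 6 in the others), so chance cannot be excluded.

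Wild-type mock replicate 3 lay between the other mock libraries and the inoculated ones. Mixing with RNA of inoculated leaves should move risen and fallen genes by the same share of the way. The median share was 0.14 for 799 risen genes (quartiles 0.05 and 0.24) and 0.6 for 697 fallen genes (0.34 and 0.74), a gap of 0.47. The gap argues against mixing as the only cause. Unequal shares were also found in other mock libraries, as given below for mutant mock replicate 2, so partial mixing cannot be excluded. A wrong inoculation label is argued against by the share of 0.14 for risen genes, and a wrong genotype label by BSK830 at 4.97 RPKM, above every mutant library. The same medians, over genes changed at least 2-fold in the wild-type response, were 0.052 (1046 risen genes) and 0.49 (1258 fallen genes) in mutant mock replicate 2. In mutant mock replicate 1 they were 0.031 (1043 genes) and 0.14 (1153 genes). The labels set no group apart for these libraries, and no biological explanation was tested.

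A few genes differed strongly between the genotypes, among them Solyc10g084960 and Solyc03g116190 under both inoculations. Of the 7 genes called in inoculated leaves, 3 were not called in mock leaves. They were Solyc01g066790, Solyc03g096430 and Solyc05g054050, with log2 differences of 3.98, 3.85 and 1.40 inoculated and 1.23, 0.926 and 0.437 in mock leaves. None of them was called for the interaction. A single chromosome segment linked to the edited gene or carried by the line is argued against, because of 12 genes besides BSK830 at most 1 lay within any 200 consecutive genes of the table. Other differences between the plant lines, such as further edits or the history of the line, may account for them and cannot be told apart from the mutation with the 1 mutant line of the series. An effect of the BSK830 mutation stays open and was not tested further.

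With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The wild-type response called 6746 genes in the real split and at most 0 in the others (1 of 10 as large), and the mutant response 3021 and at most 0 (1 of 10). For lists, 2 of 10 splits of the wild-type libraries and 3 of 10 of the mutant libraries gave as many called lists, with 7 real and at most 7 in another split. Between genotypes in inoculated leaves 2 of 10 splits called as many genes, with 7 real and 203 in the split of inoculated wild-type replicate 1 and mutant replicates 1 and 2 against the other libraries. In mock leaves it was 2 of 10, with 6 real and 2224 in the split of wild-type replicates 1 and 2 and mutant replicate 3 against the other libraries. These splits point to a structure of the samples that does not follow the genotype. For lists in mock leaves it was 4 of 10 (3 real, at most 5). Where the real count is 0, every split reaches it by construction and the share decides nothing. This holds for lists in inoculated leaves (10 of 10, at most 6) and for interaction genes (100 of 100, at most 1205). The splits exchanged libraries across replicate numbers and did not keep the libraries of replicate 1 together.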

How the results depend on the processing

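Fits on replicates 2 and 3, with a term for replicate 1, by voom, without both libraries in doubt, the mean genotype difference, and the list counts and targeted gene without each library were chosen after seeing the data; all others were fixed before. No called result changed direction. For moved values the cause was not tested, except where fewer genes, samples or a stricter threshold set it by construction. Genes called were 6746 (wild-type response), 3021 (mutant response), 7 (genotypes, inoculated), 6 (genotypes, mock), 13 (mean genotype difference) and 0 (interaction). A stricter filter gave 3, 1 and 7 for the 3 genotype counts, robust estimation with array weights 15, 18 and 21 with 12128 for the wild-type response, and a 2-fold threshold 3196 and 1612 for the responses. Fits on the 6 libraries gave 2 and 2 between genotypes. Replicates 2 and 3 alone gave 3187, 962, 0, 0 and 2, with 2 of the 13 genes of the mean difference kept. voom gave 8 for the mean difference, and the fit without both libraries in doubt 4598 for the mutant response. An estimated correlation gave 0 called lists in every comparison, against 7 in each response, 3 in mock leaves and 4 for the interaction.

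Without 1 library, genes called ranged from 3614 to 8376 (wild-type response), 954 to 4632 (mutant response), 6 to 8 (genotypes, inoculated), 3 to 5 (mock), 9 to 13 (mean difference) and 0 to 0 (interaction). The response-size difference ranged from -0.79 to -0.25, BSK830 from -1.22 to -0.988 (inoculated) and -1.14 to -1.08 (mock), where the call was lost in 4 fits. Called lists ranged from 7 to 7, 6 to 8, 0 to 2, 1 to 3, 1 to 5 and 0 to 2 for the responses, the genotypes inoculated and mock, the interaction and the mean difference. Of the listed genes called in the wild-type and mutant responses, 53 of 109 and 26 of 78 were called in every alternative.

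The libraries of replicate number 1 went together (6 of 6 pairs above a correlation of 0.1), and those of numbers 2 and 3 did not (2 and 3 of 6), so the numbers were not taken as pairs throughout. Correlations of deviations ran from 0.14 to 0.68 for number 1, -0.27 to 0.46 for number 2 and -0.63 to 0.65 for number 3, and 8 of 12 libraries were closest to one of their own number. With the number as a block, limma called 7197, 4064, 8, 4, 0 and 10 genes in the order wild-type response, mutant response, genotypes inoculated, mock, interaction and mean difference, and 7, 7, 0, 3, 4 and 0 lists. The response-size difference was -0.407 (exact p = 0.31) with the block and BSK830 stayed at -1.11. Depth, down to 10.07 M recovered reads, limits the low genes.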

Other observations

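The comparison averaged over inoculations and its splits were chosen after the separate comparisons had been seen. Averaged over both inoculations, limma called 13 genes between the genotypes, 11 higher and 2 lower in the mutant, with 378 at an unadjusted p under 0.05. BSK830 was lower by a log2 difference of -1.11 (SE 0.083, limma adjusted p = 0.000275), Solyc10g084960 higher by 4.37 and Solyc03g116190 higher by 2.37. Of 100 splits of the libraries 6 called as many genes, with 1205 in the highest, so chance cannot be excluded by splits that exchange libraries freely across replicate numbers. These splits ignore that the libraries of replicate 1 go together, and the highest one points to a structure of the samples besides genotype. With a term for replicate 1, 10 genes were called. Apart from the splits, 4 genes were called under both inoculations, against 0.00177 higher and 5.9e-05 lower ones for independent lists. Both contrasts share no library but share an estimate of spread per gene, so the lists are not independent. The shared lower gene is the edited BSK830 itself. Camera called 0 lists, with 1 at an unadjusted p under 0.05, and a count of 0 is reached by 100 of 100 splits by construction (at most 7 lists).

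Some genes were high in inoculated replicate 1 of both genotypes. The jasmonate repressor gene JAZ4 measured 9.46 RPKM in wild-type replicate 1, against 0.636 and 0.564 in replicates 2 and 3, and 9.39 against 1.41 and 2.08 RPKM in the mutant. The leucine aminopeptidase gene Solyc12g010030, a wound-responsive defence gene, measured 12.5 against 1.39 and 1.63 RPKM in wild type and 14.5 against 0.981 and 1.49 RPKM in the mutant.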
